A study of Homo sapiens with 9 samples.

How the data were processed

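RNA was measured by sequencing in cells labelled GES-1, an established line of human gastric epithelial cells, whose identity was not checked here. The labels put 9 libraries in 3 groups of 3 by the treatment and the sample title: cells never exposed to bacterial material, called wild type there, and cells kept with 2 µg/mL of a lysate of Helicobacter pylori for 1 generation or for 30 generations. Total RNA was extracted with TRIzol and libraries followed standard Illumina protocols, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

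Each library came as a table of 58735 genes with values in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), as deposited by the authors and named per the file headers. The submitters' processing notes name HISAT2, Cuffdiff and the human build hg38. The versions, the annotation and the part each tool played are not given in the sources used here. All 58735 gene identifiers (100%) were found in the reference annotation used here, GENCODE for GRCh38, and 99.9% had the same chromosome, start and end. Coordinates are printed as the tables give them, counted from 1 on hg38. A symbol was shared by more than 1 identifier for 1745 genes, and genes were therefore followed by identifier.

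Depth was read from the tables themselves. Within each library the FPKM values of genes were whole multiples of the value of 1 read for a gene of that length, in 100% of values within a tolerance of 0.1 read. The recovered reads on genes summed to between 29276462 and 47668726 per library, and stood at 0.898 to 1.20 times the total by which the values had been scaled. Between 10972 and 11963 genes reached 1 FPKM in each library. The recovered reads served to describe depth, to set replicates against counting noise and for one alternative test. Over genes with at least 20 reads in a pair of libraries, the median chi-square of 2 libraries of the same group was compared with 0.455, the value counting noise alone gives.

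FPKM values were converted to log2 after a pseudocount of 1 was added, and a fold change is the difference on that log2 scale, which understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 12675 in all, of which 10560 are protein coding. All 9 libraries entered 1 linear model with a mean for each group in limma 3.58.1 under R 4.3.3, with an intensity trend in the variance and 1 pooled spread for the 3 groups. The comparisons were 1 generation against wild type, 30 generations against wild type and 30 generations against 1 generation. The last is also the test of whether the effects at 1 and 30 generations differ. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and every adjusted p for a gene comes from limma. Genes that differed between any groups were found with limma's moderated F test and sorted by their calls in the 3 comparisons.

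A total of 36 gene lists were fixed, and 31 of them had the 5 tested members needed for a test. Lists were tested with camera from limma, which asks whether the members change more in 1 direction than the other genes, with a preset inter-gene correlation of 0.01, and adjusted over the 31 lists of a comparison. The estimated correlation and the directional test fry were alternatives. For single genes of a list, counts adjusted over the list alone stand beside those over all genes tested. The groups, the tests, the lists, the alternatives listed here as chosen in advance and the rule for naming genes were chosen before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 FPKM and no overlap between the groups, leaving out clone names, small RNAs and pseudogenes. It further took up to 4 members of each list with the smallest adjusted p, the uncalled member with the highest mean, up to 5 genes in each direction with the same call in both comparisons with wild type, and 12 fixed genes. Some genes that the rule took are not reported here. Genes outside the rule are marked in the text as chosen after their values were seen. Genes of families with near-identical copies, such as histone, GAGE, PAGE, SPRR, HLA, HSP70 and HSP90 and ribosomal protein genes, are uncertain, since the counting could divide reads among the copies.

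The comparisons with wild type share its 3 libraries. The covariance and correlation of their fold changes, the share of genes with the same sign and the overlap of calls were therefore set beside 100 simulations of unchanged groups against those libraries (20 for the overlap). These simulations drew the groups independently, and 100 further ones, chosen after seeing the data, carried over the correlation of same-numbered wild type and 30-generation libraries. All of them drew each gene independently of the others. The labels number the replicates 1 to 3 in each group, and whether the numbers pair the libraries was checked from the deviations of each library from its group mean. Same-numbered wild type and 30-generation libraries correlated across genes at 0.574, 0.377 and 0.555, each above the minimum of 0.1. Wild type replicate 2, however, lay closer to 30-generation replicate 1 (0.466) than to 30-generation replicate 2. Replicate 3 stood apart in both groups, so replicates 1 and 2 correlate whatever their numbers. The minimum therefore cannot show that these numbers pair the libraries, and no label names a shared batch. The other pairs of groups did not meet that minimum. Library and list properties were also set against 10000 random lists, in which each member was replaced by 1 of its 50 nearest genes in GC content, length and mean level.

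The scripts were tested on simulated data with known changes, drawn from the real means. Of genes changed 2-fold, 9% were recovered in the comparison of 1 generation with wild type, 7% in that of 30 generations with wild type and 18.5% in that of 30 generations with 1 generation, each over 12675 genes. For genes changed 4-fold these shares were 46%, 48% and 60.5%. Calls were made on 0.0321%, 0.0561% and 0.0978% of the genes left unchanged. In the simulation of 30 generations against wild type the 1 raised list was called, and 0 of 30 unchanged lists were called by camera. These simulations drew genes independently, with the same spread of a gene in all groups. The real groups did not spread alike, so these shares may not carry over to them.

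The alternatives chosen in advance were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, scaling by median of ratios or by a trimmed mean, quantile normalization, no intensity trend, robust estimation, sample weights, a fit with only the 6 libraries compared, the replicate number as a block, a minimum absolute log2 fold change of 1, an estimated correlation, fry, and each library left out in turn. Alternatives chosen after seeing the data were the fit without wild type replicate 3 and 30-generation replicate 3, the block within the 6 libraries compared, limma's voom on the recovered reads, and the removal of trends on GC content and gene length, for which 99.9% of tested genes had a value. Numbers were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.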

Results

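Transcript levels were measured in cells labelled GES-1, a gastric epithelial line, whose identity was not checked. Some had never met the bacterium, and others were kept with 2 µg/mL of a lysate of Helicobacter pylori, which colonises the human stomach. Exposure lasted 1 generation or 30 generations. Each group held 3 libraries. The reads on genes, recovered from the steps of the FPKM values, ranged from 29276462 to 43602899 in wild type, from 30218918 to 33414580 at 1 generation and from 32181454 to 47668726 at 30 generations. A total of 12675 genes were tested. Of the genes fixed in advance, CDX2, an intestinal marker, was listed at 0 in all 9 libraries. MUC5AC, CDH1, IL6 and TFF1 reached at most 0.072, 0.361, 0.864 and 1.82 FPKM. EPCAM, added with KRT18 to the fixed genes, reached at most 0.341 FPKM. The epithelial keratin gene KRT18 stood at 87.4 ± 21.2, 126 ± 5.43 and 104 ± 50.7 FPKM in wild type, at 1 generation and at 30 generations, and was called in no comparison. The mesenchymal filament gene VIM stood at 377 ± 192, 286 ± 0.526 and 240 ± 58.1 FPKM (SD, n = 3 in each group) and was called in none either, like CD44 and MYC. The low CDH1 and EPCAM and the abundant VIM did not bear out the epithelial label, whereas KRT18 went with it. Cell identity was thus left open.

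The libraries did not spread alike. The 3 libraries of 1 generation lay closest together, with correlations of log2 values across genes from 0.995 to 0.996, a median SD of 0.0496 on the log2 scale and a median chi-square from 0.803 to 1.18, against 0.455 from counting noise alone. They thus differed by more than counting noise and were kept as 3 replicates, though this does not show that they came from separate cultures. The median SD was 0.360 in wild type and 0.354 at 30 generations, where replicate 3 stood apart in each group. Wild type replicates 1 and 2 correlated at 0.989 with each other and at 0.850 and 0.846 with replicate 3. The 30-generation replicates 1 and 2 correlated at 0.993 with each other and at 0.881 and 0.876 with replicate 3. The libraries that stood apart correlated at 0.907 with each other and shared high levels of hypoxia and glycolysis genes. NDRG1 and RN7SL2 were chosen after their values were seen. NDRG1, a gene induced by low oxygen, measured 1114.1 FPKM in wild type replicate 3 and 500.8 FPKM in 30-generation replicate 3, and from 8.5 to 16.7 FPKM in the other 7. The small cytoplasmic RNA RN7SL2 took 0.00068% and 0.00179% of reads in these 2 libraries, and from 0.0454% to 0.204% in the others. These 2 libraries enter the values below, and the counts without them are given beside each comparison as an alternative chosen after seeing the data.

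**Figure D1:**
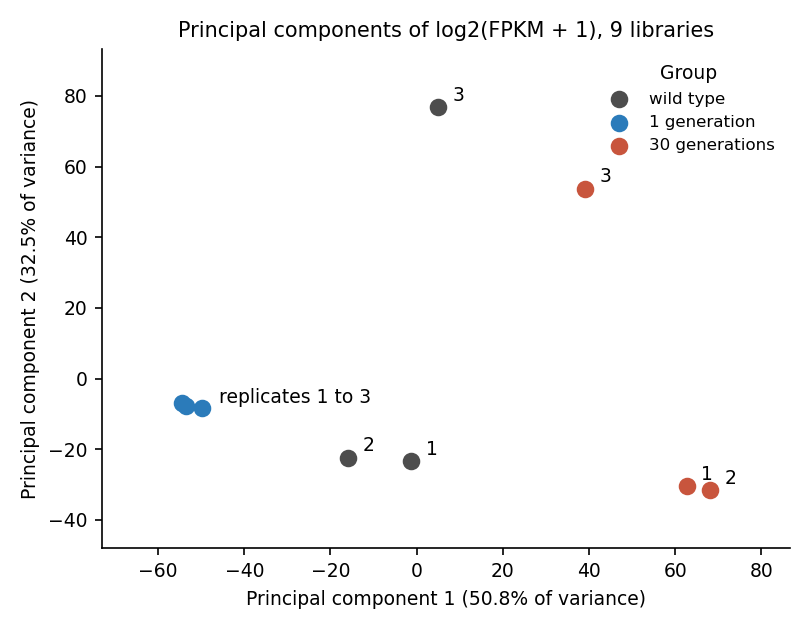
Principal components 1 and 2 of the 12675 genes tested, with 50.8% and 32.5% of the variance on the horizontal and vertical axes and 1 point for each of the 9 libraries, coloured by group and numbered by replicate. The first axis runs from 1 generation to 30 generations with wild type between them, and the second parts replicate 3 of wild type and of 30 generations from the other 7 libraries.

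The first comparison asked what differed between cells after 1 generation of exposure and wild type. The labels do not say whether each group was a culture or batch of its own. Such a difference therefore cannot be told apart from the lysate. The lists of cholesterol synthesis, heat shock and DNA replication genes were higher on average than in wild type, and those of the integrated stress response, NF-kB targets and immediate-early genes were lower on average. With an estimated correlation camera still called the cholesterol and NF-kB lists (adjusted p = 0.0289 and 0.0411) and none of the other 4 (0.0546 to 0.541). HMGCS1 (chromosome 5, 43289395 to 43313512), an enzyme of the mevalonate pathway to cholesterol, rose from 8.34 ± 1.14 to 48.2 ± 2.07 FPKM (SD, n = 3 in each group). HSPA8 (chromosome 11, 123057489 to 123063230), an HSP70 chaperone, rose from 62.9 ± 15.6 to 388 ± 5.97 FPKM. PPP1R15A (chromosome 19, 48872392 to 48876057), which restores translation after stress, fell from 185 ± 93.3 to 19.2 ± 0.854 FPKM. The log2 fold changes were 2.40 (SE 0.25, adjusted p = 0.006), 2.63 (SE 0.32, adjusted p = 0.0084) and −3.08 (SE 0.42, adjusted p = 0.012) in limma with Benjamini-Hochberg adjustment.

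Cholesterol biosynthesis gave the smallest adjusted p of the 31 lists tested at 1 generation. Of its 24 tested genes, 11 rose and 13 did not pass, and 17 rose when adjusted over the list alone. IDI1 rose by 1.82 and SQLE by 1.71 on the log2 scale (n = 3 in each group), while INSIG1, a feedback inhibitor, measured 1.63 and did not pass (adjusted p = 0.28). The list averaged 1.11 (adjusted p = 4.02e-12) and held with an estimated correlation (adjusted p = 0.0289). Among 12 genes of fatty acid synthesis, ACACA, ACLY and FADS1 rose, by 1.22, 1.06 and 0.90, and 5 rose when adjusted over the list alone. This list averaged 0.65 (adjusted p = 0.000489, and adjusted p = 0.0546 with an estimated correlation).

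Of 15 cytosolic heat shock genes, 3 rose and 12 did not pass, and 12 rose when adjusted over the list alone. Besides HSPA8, they were HSPH1, from 6.4 ± 3.69 to 25.5 ± 0.875 FPKM, and HSP90AB1, from 330 ± 29.9 to 724 ± 6.25 FPKM (SD, n = 3). HSP70 and HSP90 genes have close copies and are uncertain. The list averaged 1.17 (adjusted p = 3.57e-06, and adjusted p = 0.134 with an estimated correlation). The replicative polymerase subunit POLE2 rose by 0.98, the 1 called among 27 DNA replication genes, and 4 rose when adjusted over the list alone. That list averaged 0.87 (adjusted p = 3.13e-06, and adjusted p = 0.541 with an estimated correlation), and 0.50 without wild type replicate 3, in which these genes were low. Of 28 cell cycle and mitosis genes, TOP2A rose from 29.8 ± 7.53 to 68.1 ± 3.24 FPKM, and CENPF and TTK by 1.31 and 1.07, and 5 rose when adjusted over the list alone. Their list averaged 0.57 (adjusted p = 0.000489, and adjusted p = 0.541 with an estimated correlation). DNA repair genes averaged 0.35 (adjusted p = 0.0272, and adjusted p = 0.656 with an estimated correlation), a call lost without wild type replicate 3 (mean 0.09, adjusted p = 0.501) and with GC content and length trends removed (adjusted p = 0.06994).

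Other single genes with large rises lay outside these lists. ZNF114 (chromosome 19, 48270102 to 48287608), a zinc finger gene, rose from 3.59 ± 0.528 to 18.7 ± 0.266 FPKM (log2 fold change 2.11, SE 0.16, adjusted p = 0.0032). The thrombin receptor F2R rose from 20.5 ± 5.35 to 79.8 ± 2.28 FPKM, and TPBGL and ENC1 rose by 2.57 and 1.98 on the log2 scale. Single members rose in lists that were not called, namely OAS3 of the interferon-stimulated genes, by 1.31, the junction gene CGN, by 0.80, the oxidative pentose phosphate enzyme PGD, by 1.05, and the respiratory chain subunit NDUFB3, by 0.87.

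The integrated stress response, which halts translation and raises amino acid supply under stress, was lower at 1 generation. Of its 21 tested genes, 7 fell and 14 did not pass, and 10 fell when adjusted over the list alone. The transcription factor DDIT3 (chromosome 12, 57516588 to 57521737) fell from 35.4 ± 16.6 to 3.85 ± 0.356 FPKM and TRIB3 from 239 ± 82.1 to 45.7 ± 1.43 FPKM (SD, n = 3). CHAC1, DDIT4 and CTH fell by 1.95, 1.78 and 1.43. The list averaged −1.10 (adjusted p = 4.33e-08, and adjusted p = 0.0546 with an estimated correlation). From outside the list came INHBE, ADM2 and VGF, which fell by 2.42, 2.10 and 2.13.

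Among 17 NF-kB target genes of inflammation, the cytokines LIF and IL1A and the NF-kB subunit RELB fell, with log2 fold changes of −1.53, −1.16 and −1.50, while CSF2 measured −1.34 (adjusted p = 0.2). Adjusted over the list alone, 9 fell. The list averaged −0.80 (adjusted p = 2.7e-05) and held with an estimated correlation (adjusted p = 0.0411). The chemokine CXCL8 measured −0.47 and did not pass (adjusted p = 0.31). The cytokine IL24 (chromosome 1, 206897443 to 206904139) fell from 12.8 ± 2.86 to 0.932 ± 0.103 FPKM, and IL32 fell by 2.08. Of 21 immediate-early genes, FOSL1, IER3 and KLF4 fell, by 1.54, 1.16 and 2.04, and when adjusted over the list alone 6 fell and 1 rose. They averaged −0.98 (adjusted p = 0.000164, and adjusted p = 0.0845 with an estimated correlation). These genes were higher in wild type replicate 3 than in wild type replicates 1 and 2, by 0.73 on the mean log2 scale. Of 15 MHC class I genes, 1 fell, and 4 when adjusted over the list alone. They averaged −0.55 (adjusted p = 0.0055, and adjusted p = 0.48 with an estimated correlation), and −0.34 without wild type replicate 3, in which these genes were high. The 35 ribosomal protein genes tested averaged −0.50 (adjusted p = 2.7e-05, and adjusted p = 0.541 with an estimated correlation). None of them passed alone in limma, 9 had an unadjusted p under 0.05, and the list was not called after quantile normalization (adjusted p = 0.435).

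Members of lists that were not called also fell. The p53 targets GADD45A, SESN2, BBC3 and CDKN1A fell, with log2 fold changes of −1.50, −1.39, −0.98 and −0.97, with a list average of −0.23 over 22 genes (adjusted p = 0.349). CDKN1A (chromosome 6, 36676460 to 36687339), which stops the cell cycle, went from 258 ± 47.9 to 130 ± 3.5 FPKM. The stress cytokine GDF15, VEGFA, the matrix protease MMP9, HERPUD1 and XBP1 of the unfolded protein response, the growth factor HBEGF, GABARAP of autophagy and S100A2 of squamous epithelium fell by 1.76, 1.60, 1.79, 1.34, 1.02, 0.93, 1.71 and 1.36. Hypoxia and glycolysis genes averaged −0.74 (adjusted p = 0.0693), but 0.43 without the 2 libraries that stood apart (adjusted p = 0.000204). The 8 RNAs chosen as signs of RNA quality averaged −0.37, and all 3 libraries of 1 generation lay under all 3 of wild type, without a call by camera (adjusted p = 0.129) and with one by fry (adjusted p = 0.00141). The other lists not called by camera had means from −0.43 for replication-dependent histones (adjusted p = 0.58) to 0.24 for Wnt targets (adjusted p = 0.382). The histone mean was 0.10 without the 2 libraries that stood apart. Bacterial sensing was called higher by fry (adjusted p = 0.00236).

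In total 253 genes rose and 295 fell at 1 generation, 548 of 12675, and 2971 had an unadjusted p under 0.05. The higher and lower counts were 159 and 312 with a pseudocount of 0.1, 401 and 248 with 5, and 450 and 200 without a filter. The 3 libraries of 1 generation lay beyond all 3 of wild type for 5998 genes (47.3%) of all tested. Chance gives 10% only for libraries that are independent and spread alike. Those of 1 generation lay much closer together (median SD 0.0496 against 0.360 in wild type), so 10% is no baseline for this share. All called genes named in each comparison (60, 79 and 127) lacked overlap too, which a call with 3 libraries all but requires. The library means of all 11 called lists did not overlap either. With GC content and length trends removed, 409 genes were called, 263 of them among the 548 in the same direction. The count of 548 rested on the libraries fitted. It was 33, 1387, 7, 4, 5, 257, 252 and 2301 without wild type replicate 1, wild type replicate 3, the 1-generation replicates 1, 2 and 3, and the 30-generation replicates 1, 2 and 3, 7814 without the 2 libraries that stood apart, 1445 with only the 6 libraries compared and 976 after quantile normalization. Of the 60 called genes named, 60 kept their call without those 2 libraries, 44 with GC content and length trends removed and 1, ZNF114, kept it in all 9 fits that left out a library. Without those 2 libraries most genes tested were called, so keeping a call there says little. With only the 6 libraries compared 60 kept it, and with the replicate block within them 0.

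**Figure D2:**
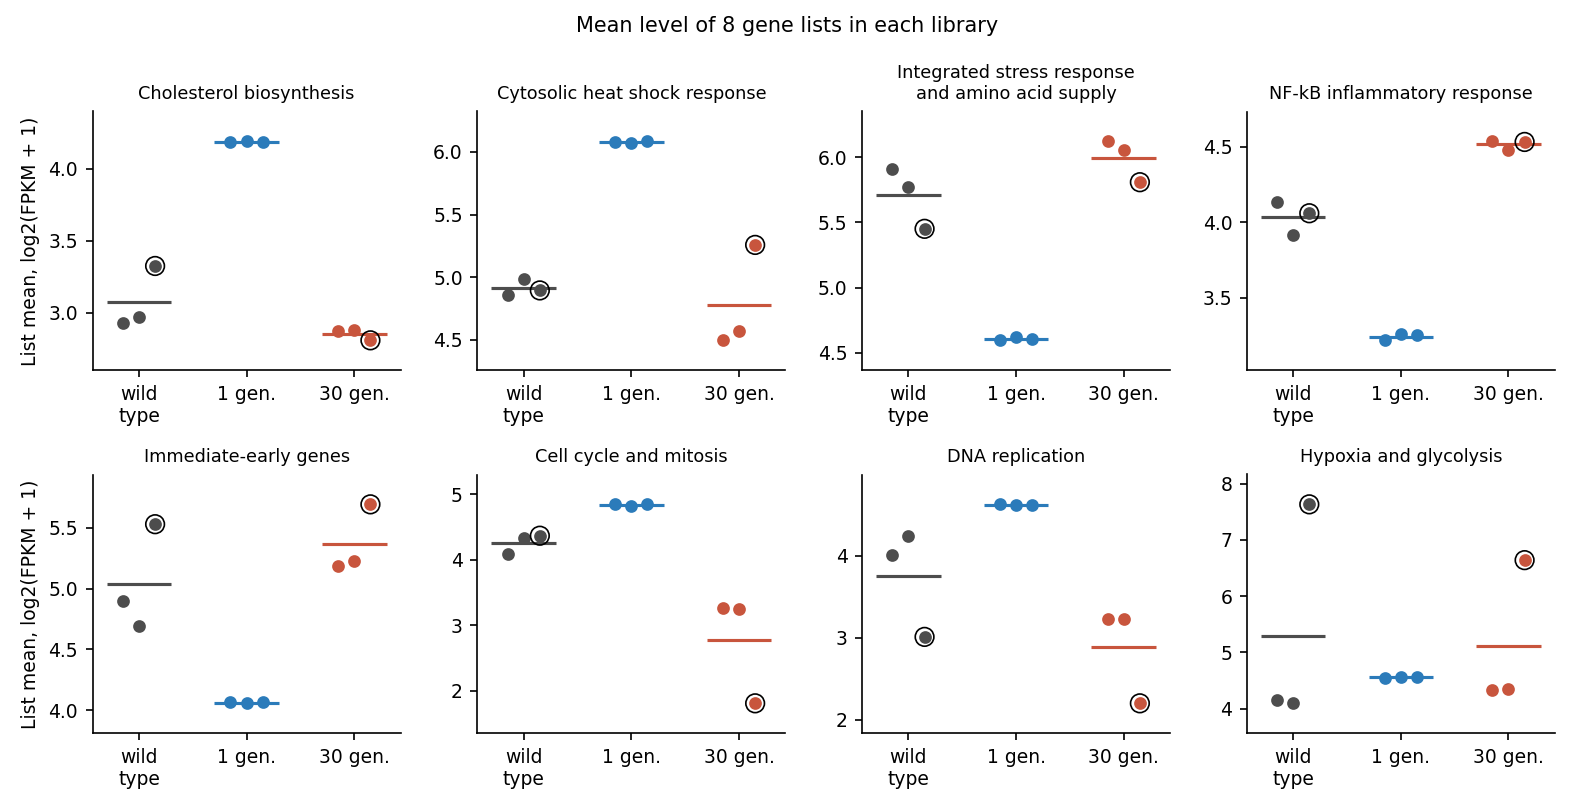
Mean log2(FPKM + 1) of 8 gene lists in each library, with 1 point for each of the 3 libraries of a group, a line at the group mean and open circles for replicate 3 of wild type and of 30 generations. Cholesterol and heat shock genes peak and integrated stress response genes dip at 1 generation, cell cycle and DNA replication genes are lowest at 30 generations, and hypoxia genes part the open circles from the other libraries.

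The comparison of 30 generations with wild type asked how cells differed after long exposure. There were 0 unexposed libraries grown for 30 generations. Longer time in culture therefore cannot be told apart from the lysate in any difference of this comparison. The lists of mitosis and DNA replication genes were lower on average than in wild type, and p53 targets, NF-kB targets and genes of the respiratory chain were higher on average. No list was called by camera with an estimated correlation (adjusted p from 0.547 to 0.805 for the 12 lists called at the preset one), and the p53 and NF-kB lists were not called without the 2 libraries that stood apart (adjusted p = 0.371 and 0.067). TOP2A (chromosome 17, 40388516 to 40417950), the topoisomerase that untangles DNA in dividing cells, fell from 29.8 ± 7.53 to 1.8 ± 0.459 FPKM (SD, n = 3 in each group). The proliferation marker MKI67 (chromosome 10, 128096659 to 128126385) fell from 19.3 ± 8.28 to 3.01 ± 1.41 FPKM. CDKN1A rose from 258 ± 47.9 to 487 ± 28 FPKM. The log2 fold changes were −3.44 (SE 0.23, adjusted p = 0.00085), −2.32 (SE 0.34, adjusted p = 0.0065) and 0.93 (SE 0.21, adjusted p = 0.022) in limma with Benjamini-Hochberg adjustment.

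Of 28 cell cycle and mitosis genes tested, 15 fell and 13 did not pass, and 16 fell when adjusted over the list alone. CENPF (chromosome 1, 214603195 to 214664588), a kinetochore protein, fell from 8.57 ± 3.62 to 0.707 ± 0.282 FPKM, and the spindle checkpoint kinases BUB1B and TTK fell by 2.30 and 1.95. The list averaged −1.49 (adjusted p = 9.44e-08, and adjusted p = 0.547 with an estimated correlation), and −0.95 without the 2 libraries that stood apart (adjusted p = 0.000467). These genes were lower in 30-generation replicate 3 than in replicates 1 and 2, by a mean of −1.44 on the log2 scale. Of 27 DNA replication genes, 8 fell, and 9 when adjusted over the list alone, with RRM1 falling by 2.10, ORC1 by 1.63 and RFC5 by 1.11. They averaged −0.86 (adjusted p = 0.00048, and adjusted p = 0.676 with an estimated correlation). Replication genes measured −1.11 and −1.03 in the libraries that stood apart, relative to the others of their groups. Of 27 DNA repair genes, 6 fell, and 9 when adjusted over the list alone, among them BRCA1 by 1.60, FANCD2 by 1.40, MSH6 by 1.72 and EXO1 by 1.97. They averaged −0.56 (adjusted p = 0.0312, and adjusted p = 0.707 with an estimated correlation). Further genes of mitosis outside the lists, ANLN, DLGAP5, KIF4A, ECT2 and NEK2, fell by 2.92, 2.84, 2.39, 2.35 and 2.30, as did ARHGAP18, by 2.41.

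Of 22 p53 targets, 7 rose and 15 did not pass, and when adjusted over the list alone 8 rose and 3 fell. TP53I3 rose from 21.1 ± 7.16 to 65.3 ± 9.22 FPKM (SD, n = 3), GADD45A by 1.37 and the nuclease AEN by 1.16. P53 targets averaged 0.34 (adjusted p = 0.0365, and adjusted p = 0.564 with an estimated correlation), and 0.22 without the 2 libraries that stood apart (adjusted p = 0.371). Among 17 NF-kB targets, RELB and CXCL8 rose, by 1.05 and 1.43, and 6 rose when adjusted over the list alone. CXCL8 (chromosome 4, 73740506 to 73743716), a chemokine that draws neutrophils, went from 0.525 ± 0.179 to 3.28 ± 1.48 FPKM. NF-kB targets averaged 0.48 (adjusted p = 0.0312, and adjusted p = 0.547 with an estimated correlation), and 0.48 without the 2 libraries that stood apart (adjusted p = 0.067). Of 21 immediate-early genes, DUSP5, FOSL1 and IER3 rose, by 1.18, 0.93 and 0.80, and 3 rose when adjusted over the list alone. They averaged 0.33 (adjusted p = 0.0312, and adjusted p = 0.547 with an estimated correlation), and were 0.73 and 0.49 higher in the 2 libraries that stood apart than in the others of their groups. Their mean lay inside the central range of random lists matched on GC content, length and level (percentile 95.27), and the call was lost with those trends removed (adjusted p = 0.2912). In the MHC class I list of 15 genes HLA-F rose by 0.79 and the peptide-trimming enzyme ERAP2 fell by 1.58, with 1 rise and 2 falls when adjusted over the list alone. That list averaged 0.42 (adjusted p = 0.0312, and adjusted p = 0.564 with an estimated correlation), and 0.74 without the 2 libraries that stood apart (adjusted p = 0.0081).

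Other lists were called higher as well. Of 27 nuclear-encoded genes of oxidative phosphorylation, NDUFB3 and NDUFB9 rose, by 0.78 and 0.95, and 2 rose when adjusted over the list alone. They averaged 0.45 (adjusted p = 0.00048, and adjusted p = 0.564 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.079). The autophagy receptor SQSTM1 rose from 66 ± 9.08 to 167 ± 34.1 FPKM and the proton pump subunit ATP6V0D1 by 0.63, in a list of 22 genes with 3 rises and 2 falls when adjusted over the list alone. Autophagy genes averaged 0.28 (adjusted p = 0.0365, and adjusted p = 0.564 with an estimated correlation), and 0.35 without the 2 libraries that stood apart (adjusted p = 0.0752). Of 18 genes of the NRF2 oxidative stress response, NQO1 rose by 1.06 and TALDO1 by 0.92, and 2 rose when adjusted over the list alone. These averaged 0.34 (adjusted p = 0.0327, and adjusted p = 0.547 with an estimated correlation), and 0.23 without the 2 libraries that stood apart (adjusted p = 0.17). HIST1H2BK and HIST1H2BJ rose, by 2.04 and 1.17, among 10 histone genes, which have close copies, and 2 rose when adjusted over the list alone. Histone genes averaged 1.07 (adjusted p = 0.0312, and adjusted p = 0.564 with an estimated correlation), and stood 1.60 and 1.15 higher in the 2 libraries that stood apart than in the others of their groups. Ribosomal protein genes averaged 0.27 (adjusted p = 0.0312, and adjusted p = 0.805 with an estimated correlation), with none passing alone in limma, 3 at an unadjusted p under 0.05, and no call after quantile normalization (adjusted p = 0.988). They averaged 0.60 without the 2 libraries that stood apart (adjusted p = 0.000142).

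The largest single rise was that of the cancer-testis gene GAGE12E (chromosome X, 49551333 to 49558649), from 0.07 ± 0.0184 to 34.2 ± 16.3 FPKM, which has near-identical copies and is uncertain. IL24 rose from 12.8 ± 2.86 to 180 ± 196 FPKM, with 60.9, 72.7 and 406 FPKM in replicates 1, 2 and 3, the uridine phosphorylase UPP1 by 1.70, the EGF receptor ligand AREG by 1.88 and SPRR2D by 2.16. TRNP1, SNHG15 and ALOX5AP rose by 1.55, 1.54 and 1.53. Members of lists not called moved too. GDF15, HBEGF, S100A2, ISG15 and BCL2L1 rose, by 1.27, 0.83, 1.32, 1.34 and 0.79. The chaperones HSP90AA1, HSP90B1 and HSPD1 fell by 2.23, 1.83 and 1.38, HMGCS1 by 1.28, the acyl-CoA synthetase ACSL3 by 1.22, DDX58 by 1.14, ZEB1 by 1.10, NT5E by 1.43, the desmosomal cadherin DSG2 by 1.29 and the receptor TLR6 by 0.53. The integrated stress response averaged 0.28 (adjusted p = 0.108) with none of 21 genes passing in limma and 3 at an unadjusted p under 0.05, and cholesterol genes averaged −0.22 (adjusted p = 0.477). The remaining lists not called by camera had means from −0.27 for epithelial junctions (adjusted p = 0.901) to 0.41 for squamous markers (adjusted p = 0.144). These means were −0.02 and 0.70 without the 2 libraries that stood apart.

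In total 503 genes rose and 1377 fell, 1880 of 12675, and 4029 had an unadjusted p under 0.05. The groups did not overlap for 3568 genes (28.2%), where chance gives 10% if the libraries are independent, which the labels do not show. For 5 of the 12 called lists all 3 library means at 30 generations lay beyond all 3 of wild type. The count of 1880 depended on the libraries that enter the pooled estimate of the spread. The libraries of 1 generation, no part of this comparison, lower that estimate (median SD 0.0496 against 0.360 in wild type and 0.354 at 30 generations). The SEs and adjusted p given for this comparison therefore lean towards calls. With only the 6 libraries compared, 2 genes were called, GAGE12E and TOP2A, with 2609 at an unadjusted p under 0.05. With the replicate number as a block within these 6 libraries, which the numbers pair at most in part, limma called 0 genes and 4279 had an unadjusted p under 0.05. The count was 969, 448, 3909, 892, 917, 866, 606, 573 and 4882 without wild type replicates 1, 2 and 3, the 1-generation replicates 1, 2 and 3, and the 30-generation replicates 1, 2 and 3, and 9718 without the 2 libraries that stood apart. The share of higher genes among calls, 26.8%, moved to 41.6% with trimmed mean scaling and 42.0% with quantile normalization, 52.6% with sample weights and 54.3% without the 2 libraries that stood apart (5278 higher, 4440 lower), so the majority of falls depended on the processing. Trimmed mean scaling moved the median log2 fold change of all genes to 0.11. With GC content and length trends removed, 577 genes were called, 366 of them among the 1880 in the same direction.

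Of the 79 called genes named, 79 kept their call without the 2 libraries that stood apart, 27 with GC content and length trends removed and 22 in all 9 fits that left out a library. The latter include TOP2A, CENPF, MKI67, BUB1B, RRM1, BRCA1, TP53I3, SQSTM1, UPP1 and GAGE12E. Without the 2 libraries that stood apart most genes tested were called, so keeping a call there says little. With only the 6 libraries compared 2 of the 79 kept it, and with the replicate block within them 0. Of the 12 called lists, cell cycle and oxidative phosphorylation kept their call in these 9 fits. DNA replication was not called without 30-generation replicate 3 (mean −0.52, adjusted p = 0.164). Immediate-early genes, DNA repair, histones, autophagy and the NRF2 response were each not called without wild type replicate 1, wild type replicate 2 or 30-generation replicate 3, with adjusted p up to 0.270, 0.270, 0.270, 0.317 and 0.428. Without that replicate 3 their means were 0.16, −0.45, 0.69, 0.16 and 0.17. NF-kB targets lost the call without wild type replicate 2 or 3 (adjusted p up to 0.0771), with means of 0.42 and 0.49 near the 0.48 of all libraries. P53 targets lost it without either of these or 30-generation replicate 3 (adjusted p up to 0.317), with means of 0.33, 0.31 and 0.26. MHC class I and ribosomal protein genes lost it without wild type replicate 1, wild type replicate 2 or 30-generation replicate 1, and besides without 30-generation replicate 3 and replicate 2, respectively (adjusted p up to 0.0941 and 0.138), with means from 0.28 to 0.54 and from 0.15 to 0.23. With GC content and length trends removed, MHC class I, DNA repair, ribosomal protein and histone genes were not called either (adjusted p = 0.08636, 0.07183, 0.07594 and 0.1152).

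**Figure D3:**
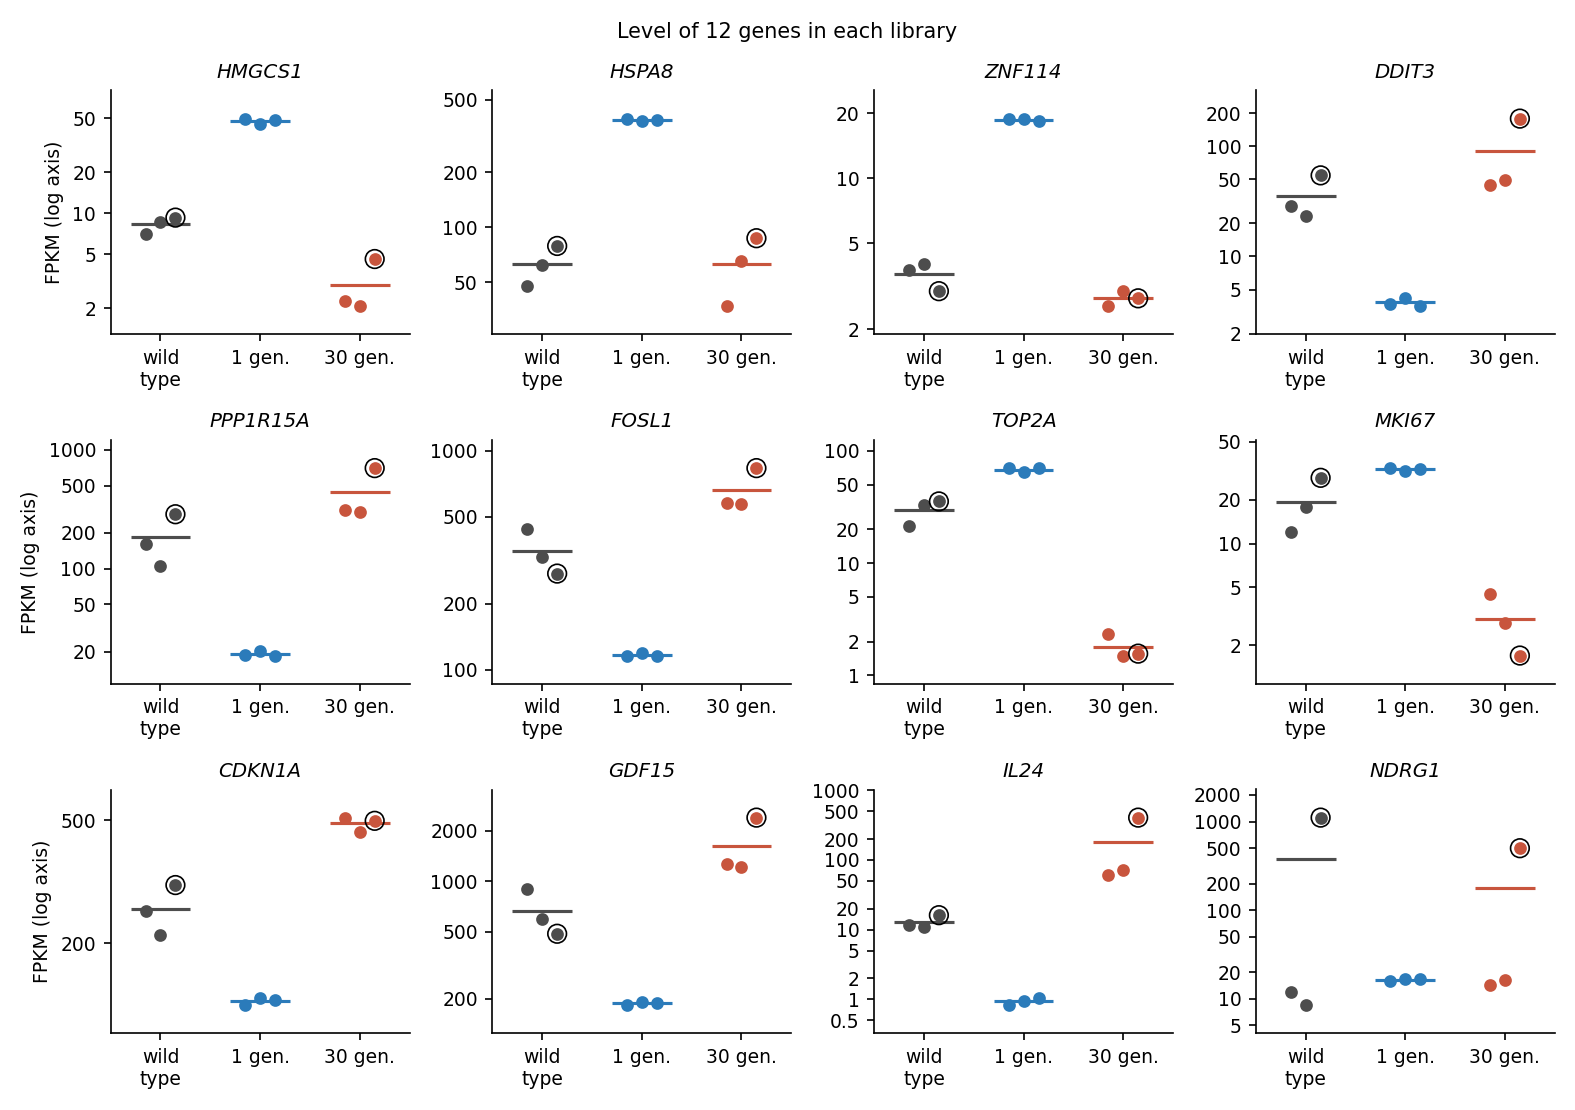
FPKM of 12 genes in each library on a log axis, with 1 point for each of the 3 libraries of a group, a line at the group mean and open circles for replicate 3 of wild type and of 30 generations. HMGCS1, HSPA8 and ZNF114 peak at 1 generation, TOP2A and MKI67 are lowest and CDKN1A, GDF15 and IL24 highest at 30 generations, and NDRG1 parts the open circles from the other 7 libraries.

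The comparison of 30 generations with 1 generation asked whether long and short exposure differed, and it held the largest differences. Here too, time in culture cannot be told apart from the length of exposure. The lists of cell division, cholesterol synthesis and heat shock genes were lower on average at 30 generations, and those of the integrated stress response, inflammation and MHC class I presentation were higher on average. No list was called by camera with an estimated correlation (adjusted p from 0.133 to 0.572 for the 14 lists called at the preset one). TOP2A went from 68.1 ± 3.24 at 1 generation to 1.8 ± 0.459 FPKM at 30 generations, and HMGCS1 from 48.2 ± 2.07 to 2.97 ± 1.41 FPKM (SD, n = 3 in each group). IL24 went from 0.932 ± 0.103 to 180 ± 196 FPKM, with 406 FPKM in replicate 3, which stood apart, and PPP1R15A from 19.2 ± 0.854 to 438 ± 228 FPKM. Their log2 fold changes were −4.64 (SE 0.23, adjusted p = 0.00012), −3.68 (SE 0.25, adjusted p = 0.00013), 5.99 (SE 0.61, adjusted p = 0.00034) and 4.33 (SE 0.42, adjusted p = 0.0003) in limma with Benjamini-Hochberg adjustment.

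Of 28 cell cycle and mitosis genes, 16 fell and 12 did not pass, with 16 falls when adjusted over the list alone. CENPF fell by 3.74, BUB1B and TTK each by 3.03 and MKI67 by 3.12, as did DLGAP5, NCAPG, SMC4 and HMMR from outside the list, with log2 fold changes of −3.63, −3.60, −3.58 and −3.43. The list averaged −2.06 (adjusted p = 1.77e-06, and adjusted p = 0.459 with an estimated correlation), and −1.58 without the 2 libraries that stood apart (adjusted p = 0.00017). Of 27 DNA replication genes, 19 fell and 8 did not pass, and 20 fell when adjusted over the list alone, with RRM1 at −3.04 and MCM10 at −2.82. They averaged −1.73 (adjusted p = 1.87e-06, and adjusted p = 0.498 with an estimated correlation). Of 27 DNA repair genes, 14 fell, among them FANCI at −2.82, and 2 rose, ERCC1 (adjusted p = 0.0018) and XRCC1 (adjusted p = 0.049), a pair named after their values were seen, and these counts were the same when adjusted over the list alone. DNA repair averaged −0.91 (adjusted p = 0.00807, and adjusted p = 0.572 with an estimated correlation).

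Of 24 cholesterol genes, 15 fell, and 18 when adjusted over the list alone, with IDI1 falling by 2.53, while TM7SF2, named after its value was seen, rose by 0.78. The cholesterol list averaged −1.33 (adjusted p = 2.56e-05, and adjusted p = 0.133 with an estimated correlation). Of 12 fatty acid genes, 8 fell, and 8 when adjusted over the list alone, including ACSL3 by 2.04 and ACACA by 1.56. They averaged −0.91 (adjusted p = 0.0124, and adjusted p = 0.154 with an estimated correlation), and −0.93 without the 2 libraries that stood apart (adjusted p = 0.0564). Of 15 heat shock genes, 8 fell, and 8 when adjusted over the list alone, with HSP90AA1 going from 196 ± 8.59 to 17 ± 15.8 FPKM and HSPA8 back from 388 ± 5.97 to 63.1 ± 25.1 FPKM. Heat shock genes averaged −1.30 (adjusted p = 0.00807, and adjusted p = 0.498 with an estimated correlation). The thrombin receptor F2R fell by 3.51.

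Of 21 integrated stress response genes, 12 rose and 9 did not pass, with 12 rises when adjusted over the list alone. DDIT3 rose by 3.95, TRIB3 by 2.93 and CHAC1 by 2.46. The list averaged 1.39 (adjusted p = 9.36e-05, and adjusted p = 0.154 with an estimated correlation). Of 17 NF-kB targets, 11 rose and SOD2, named after its value was seen, fell by 0.64, and 12 rose and 2 fell when adjusted over the list alone. RELB rose by 2.55, LIF by 2.30 and ICAM1, an adhesion molecule for leukocytes, by 1.45, and the inhibitor NFKBIA by 1.49. NF-kB targets averaged 1.27 (adjusted p = 0.000324, and adjusted p = 0.133 with an estimated correlation). Of 21 immediate-early genes, 10 rose, led by EGR1 at 3.87 and FOSL1 at 2.46, and KLF6, named after its value was seen, fell by 1.39, with 13 rises and 1 fall when adjusted over the list alone. They averaged 1.30 (adjusted p = 0.000454, and adjusted p = 0.154 with an estimated correlation).

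Of 15 MHC class I genes, 11 rose and ERAP2 fell by 2.07, and adjusted over the list alone 11 rose and 2 fell. HLA-F rose by 1.57 and the immunoproteasome subunit PSMB9 by 1.24. The list averaged 0.97 (adjusted p = 0.00452, and adjusted p = 0.498 with an estimated correlation). Of 35 ribosomal protein genes, 17 rose, among them RPL35 by 1.35 and RPS15 by 1.01, and RPL7, named after its value was seen, fell by 0.55, with 19 rises and 1 fall when adjusted over the list alone. They averaged 0.78 (adjusted p = 9.36e-05, and adjusted p = 0.549 with an estimated correlation), and the list was not called after quantile normalization (adjusted p = 0.594). Of 27 oxidative phosphorylation genes, 5 rose, led by NDUFB9 at 1.26, and ATP5F1A fell by 1.00, and these counts were the same when adjusted over the list alone. This list averaged 0.54 (adjusted p = 0.00807, and adjusted p = 0.572 with an estimated correlation) and was not called after quantile normalization (adjusted p = 0.550). Of 22 autophagy and lysosome genes, 7 rose, among them SQSTM1 by 1.61 and MAP1LC3B by 1.38, and 2 fell, with the same counts when adjusted over the list alone. They averaged 0.61 (adjusted p = 0.0154, and adjusted p = 0.498 with an estimated correlation), a call lost without 30-generation replicate 3 (mean 0.48, adjusted p = 0.0985) or without both libraries that stood apart (adjusted p = 0.0765). Of 10 histone genes, 5 rose, and 5 when adjusted over the list alone, with HIST1H1C going from 9.2 ± 0.821 to 129 ± 140 FPKM. Histone genes were higher on average (adjusted p = 0.0196, and adjusted p = 0.518 with an estimated correlation), a call lost without 30-generation replicate 3 (mean 1.12, adjusted p = 0.127) or with GC content and length trends removed (adjusted p = 0.1561).

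The p53 targets moved in both directions and averaged 0.57 (adjusted p = 0.0656). CDKN1A, GADD45A, SESN2 and BBC3 were among 11 that rose, by 1.90, 2.87, 2.22 and 1.82, and 4 fell, MDM2, RRM2B, SESN1 and ZMAT3, by 1.67, 1.73, 1.42 and 1.28, named after their values were seen. Interferon-stimulated genes split likewise, with 4 that rose, including ISG15 by 2.00 and IRF7 by 1.77, and 5 that fell (list mean 0.02, adjusted p = 0.867). Of the markers of other cell types, COL6A1 and COL6A2 rose and PDGFRB and LUM fell, by 1.64, 1.69, 1.42 and 1.19, among 7 fibroblast markers (list mean −0.02, adjusted p = 0.867). Among 8 RNAs chosen as signs of RNA quality, 3 fell, among them the long nuclear RNA MALAT1 by 1.76. Another 4 rose, among them the snoRNA host genes GAS5, SNHG12 and SNHG5 by 2.67, 1.27 and 0.97. The list mean was 0.23, without a call by camera (adjusted p = 0.59). All 3 library means at 30 generations nevertheless lay above all 3 at 1 generation. Camera did not call the lists of epithelial junctions, mesenchymal genes, bacterial sensing, apoptosis, the unfolded protein response, YAP, Wnt, TGF-beta and growth factor genes. Their adjusted p were 0.867, 0.971, 0.643, 0.97, 0.897, 0.971, 0.643, 0.876 and 0.331 in that order. Neither did it call the NRF2 response (0.867), squamous markers (0.499), hypoxia and glycolysis (0.266) and mitochondrially encoded mRNAs (0.876). In this comparison fry called 20 of the 31 lists against 14 by camera, so some lists of this paragraph passed fry. Across the 31 lists, the mean, the median and the camera direction differed in sign for 5 lists at 1 generation and 6 at 30 generations against wild type and for 4 between the exposures, none of them called by camera.

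In total 2484 genes rose and 3115 fell, 5599 of 12675, and 6691 had an unadjusted p under 0.05. The groups did not overlap for 8277 genes (65.3%), or for the library means of all 14 called lists. Chance gives 10% of genes only for independent libraries that spread alike, and those of 1 generation lay much closer together. The count of called genes ranged from 3768 without 1-generation replicate 1 to 7555 without 30-generation replicate 3. It was 10969 without the 2 libraries that stood apart. With GC content and length trends removed, 3288 genes were called, 2296 of them among the 5599 in the same direction and 39 in the opposite one. Of the 127 called genes named, 117 kept their call in all 9 fits that left out a library, 127 without the 2 libraries that stood apart and 105 with GC content and length trends removed. Without the 2 libraries most genes tested were called, so keeping a call there says little. With only the 6 libraries compared 127 kept it, and with the replicate block within them 125.

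Across all 12675 genes, the changes at 1 and at 30 generations against wild type tended to run in opposite directions, though 34.4% of genes had the same sign. Their covariance was −0.1256, against 0.1092 (SD 0.00332) in 100 simulations of unchanged groups with the same wild type libraries, a difference of −0.2348. Another simulation, chosen after seeing the data, carried over the correlation of same-numbered wild type and 30-generation libraries. It gave a covariance of 0.06875 (SD 0.00219). Both drew each gene independently, so their SDs do not measure how far a covariance varies when genes move together. The distance from the observed value can therefore not be counted in these SDs. The observed value was −0.0327 with GC content and length trends removed, and ranged from −0.1332 to −0.05673 when a library was left out. Pearson's r across genes, which are not independent, was −0.365 against 0.716 simulated, or 0.577 with that correlation of libraries carried over. The simulated share of genes with the same sign was 74.3%, or 66.8% with it carried over. A total of 134 genes were called in both comparisons in opposite directions, 79 higher at 1 and lower at 30 generations and 55 the reverse, where independent lists of these sizes give 27.49 and 11.71. The former hold HMGCS1, F2R, TOP2A and CENPF, and the latter IL24, SPRR2D, RELB, GDF15, UPP1 and CDKN1A. Only 13 genes were called in the same direction in both, 9 higher and 4 lower, against 10.04 and 32.05 for independent lists and 2.45 (SD 3.12) in 20 simulations. They include PAGE1, NDUFB3, CLP1 and ACTR5, which rose by 1.15, 0.87, 0.90 and 0.78 at 1 generation and by 0.98, 0.78, 0.74 and 0.63 at 30 generations, and GFPT1 and RCAN1, which fell by 0.94 and 0.93 and by 1.13 and 0.75. The 3 wild type libraries cannot be split into groups of 2 libraries each, so part of any shared direction may come from the shared libraries. The simulated overlap of 2.45 cannot settle this, since unchanged groups need not give as many calls as the real ones. When 1 library was left out, the number of opposite calls ranged from 0, without each 1-generation replicate in turn, to 1078, without 30-generation replicate 3. Other settings, given below, went higher. With the replicate block within the 6 libraries compared, limma called 0 genes in either comparison with wild type, which leaves no opposite calls.

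**Figure D4:**
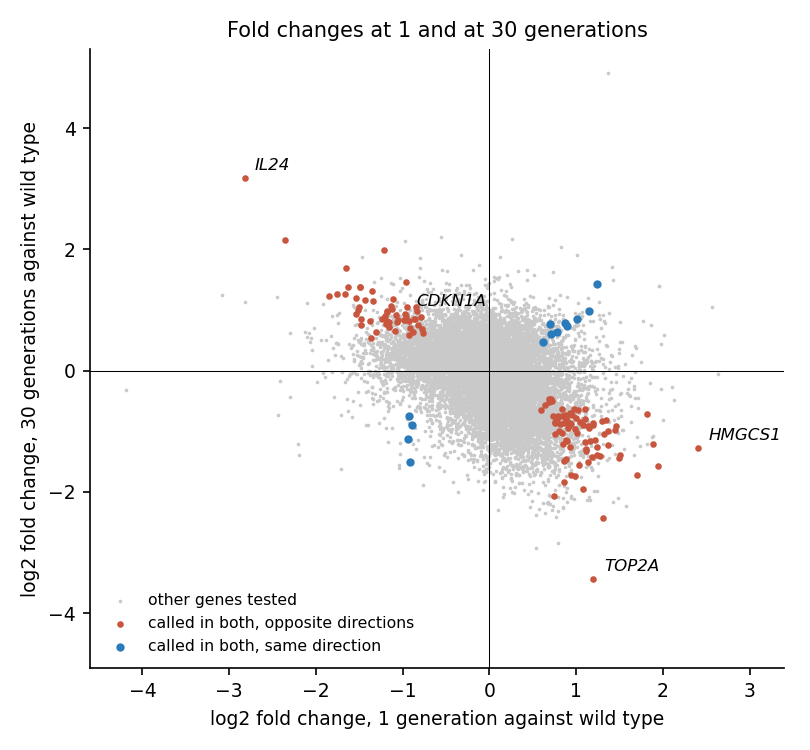
Log2 fold change at 30 generations against that at 1 generation, each relative to wild type, with 1 point for each of the 12675 genes. Genes called in both comparisons are coloured, 134 in opposite directions, such as HMGCS1 and TOP2A to the lower right and IL24 and CDKN1A to the upper left, and 13 in the same direction.

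The F test found 4618 genes that differed between any of the 3 groups, and 2487 to 7087 when 1 library was left out. The classes below rest on the calls of the main fit. Those against wild type fell to 0 in limma with the replicate block within the 6 libraries compared. The most frequent pattern, with 1276 genes (27.6%), was a level at 30 generations below that of both other groups, as for MKI67, BUB1B and BRCA1. Another 385 genes (8.34%) were higher at 30 generations than in both other groups, as were TP53I3, SQSTM1 and AREG. In 1178 genes (25.5%) and 1125 genes (24.4%) the exposures differed from each other, higher or lower at 30 generations, without a call against wild type. A further 233 genes (5.05%) were lower and 162 (3.51%) higher at 1 generation than in both other groups, as were DDIT3 and TRIB3 among the former and HSPA8 and ZNF114 among the latter.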

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

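The 4 tests on the libraries that stood apart and the test of cell cycle genes without those 2 libraries were chosen only after the result was seen. The splits of the libraries were fixed before. The other tests, on cell cycle, cholesterol and stress response genes, name the direction of the result or wild type replicate 3. They are therefore not claimed as fixed before the result was seen. The results listed here were singled out because a gene or list was called at 1 generation and at 30 generations against wild type in opposite directions, and the difference between the exposures was itself called. For a gene that last call was fixed by the other 2 and adds no support. Its fold change between the exposures is their difference, with the same SE. A list mean between the exposures is likewise the difference of the other 2 means. Values are log2 fold changes at 30 generations against 1 generation, with those at 1 and at 30 generations against wild type in brackets.

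The lists were called by camera at the preset correlation. With an estimated correlation none of the 7 was called at 30 generations against wild type or between the exposures (adjusted p from 0.133 to 0.805), and NF-kB targets alone were at 1 generation (0.0411). For lists, the mean was −2.06 for cell cycle and mitosis (0.57, −1.49), −1.73 for DNA replication (0.87, −0.86), −0.91 for DNA repair (0.35, −0.56), 1.30 for immediate-early genes (−0.98, 0.33), 1.27 for NF-kB targets (−0.80, 0.48), 0.97 for MHC class I presentation (−0.55, 0.42) and 0.78 for cytosolic ribosomal proteins (−0.50, 0.27). For genes of division, it was −4.64 for TOP2A (−3.44 at 30 generations), −3.74 for CENPF (1.31, −2.43), −3.43 for HMMR (1.71, −1.72), −3.03 for TTK (1.07, −1.95) and −1.94 for POLE2 (0.98, −0.95). For sterol genes, it was −3.68 for HMGCS1 (2.40, −1.28), −2.53 for IDI1 (1.82, −0.71) and −2.36 for STARD4 (1.36 at 1 generation), and it was −3.51 for the thrombin receptor F2R (1.94, −1.57). Genes lowest at 1 generation included IL24 at 5.99 (−2.82, 3.17), RELB at 2.55 (−1.50, 1.05), FOSL1 at 2.46 (−1.54, 0.93) and IER3 at 1.96 (−1.16, 0.80) of inflammation and early response. They also included the p53 targets GADD45A at 2.87 (−1.50, 1.37), CDKN1A at 1.90 (−0.97, 0.93) and BBC3 at 1.82 (−0.98, 0.84), and the secreted factors GDF15 at 3.03 (−1.76, 1.27) and HBEGF at 1.75 (−0.93, 0.83). The p53 list as a whole was not called by camera between the exposures (mean 0.57, adjusted p = 0.0656), and its members MDM2, RRM2B, SESN1 and ZMAT3 fell. The epithelial genes SPRR2D and S100A2 stood at 4.51 (−2.35, 2.16) and 2.67 (−1.36, 1.32), and UPP1 at 3.36 (−1.66, 1.70).

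Replicate 3 of wild type and replicate 3 of 30 generations stood apart from the other 7 libraries, and the 4 tests on them were chosen after that was seen. A swap of their labels was spoken against, since each correlated more with its own group, at 0.848 against 0.815 and 0.878 against 0.856, a smaller difference of 0.0223. Only 1 gene, PRTN3, reached 3 FPKM in both while staying under 0.3 FPKM in the 7 others. This speaks against 1 foreign line in both libraries that has many genes of its own. A related line, a mixture or a different line in each would not be seen this way. The cut-offs were set after the libraries were seen. Another library preparation and a culture state with low oxygen were left open, since RN7SL2 lay at least 25.3-fold under the lowest of the 7 others and the hypoxia and glycolysis list at percentile 100 of matched random lists in both. These values measure the differences that prompted the tests and are no separate evidence for either.

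Cell cycle genes were lower at 30 generations than at 1 generation. The test without the 2 libraries was chosen after this was seen, and the others name its direction. A GC content and gene length trend was spoken against, since the list mean of −2.06 lay at percentile 0 of random lists matched on GC content, length and level. The libraries that stood apart did not carry it, since the mean without those 2 libraries was 0.766 of that with them. Longer time in culture could not be told apart from the lysate, since there were 0 unexposed libraries grown for 30 generations.

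Cholesterol genes were higher and integrated stress response genes lower at 1 generation than in wild type. The tests name these directions and are not claimed as fixed before. With an estimated correlation camera did not call the stress response list (adjusted p = 0.0546). A GC content and gene length trend was spoken against for both, with the cholesterol mean at percentile 100 and the stress response mean at percentile 0 of matched random lists. Wild type replicate 3 was spoken against as the source, since the means without it were 1.11 and 1.12 of those with it.

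The splits of 6 libraries are too few for a small share, which is never under 0.1 with 10 splits. For genes, 1 of 10 splits, the real one, gave a count as large in each comparison, with 548, 1880 and 5599 genes. In limma the highest other count was 0 genes, while up to 325, 3967 and 795 genes had an unadjusted p under 0.05, where the real splits had 2971, 4029 and 6691. The split with 3967 set wild type replicate 1 and 30-generation replicates 1 and 2 against the others, and thus parted the libraries that stood apart from most of the rest. For lists, 4 of 10 splits at 1 generation against wild type called as many as the real 11, with 13 at most, and 4 of 10 between the exposures called as many as the real 14, with 15 at most. Counts of called lists in these comparisons thus do not speak for the grouping, and whether the structure of the samples or the preset correlation gives such counts was not tested. At 30 generations against wild type 1 of 10 splits gave as many as the real 12 lists, with 10 at most, and the other splits that part all 3 numbered pairs gave 0 genes in limma (2084, 31 and 52 at an unadjusted p under 0.05) and 5, 7 and 10 lists. Of 100 splits of the 9 libraries into 3 groups, drawn from 280 possible, 1, the real one, gave as many genes in the F test as the real 4618, and the highest other gave 1986, which speaks against a random grouping as the source. Libraries of a group that are alike for any reason, such as a shared culture or batch, could give this too. It therefore does not speak for the lysate.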

How the results depend on the processing

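Directions of called genes held under most settings, apart from the turned values below, while the counts depended on the libraries fitted and on the size of the spread. Over the planned settings that left out a library in turn, values of named genes, called or not, kept direction and side of the threshold in 3842 cases, lost the call in 606, gained it in 185 and turned in 2. For lists these numbers were 798, 32, 6 and 1. Median-of-ratios and trimmed mean scaling, no intensity trend, the robust fit and voom on recovered read counts left the total number of genes and of lists called within 1.5 times of the main one in each comparison. Tests set aside for files of raw counts were not run, since the files hold FPKM, and the recovered reads were tested with voom alone. Depth, from 29276462 to 47668726 reads on genes, limits what can be said of genes under 1 FPKM, which were not tested. Where no construction is named below, the cause was not tested.

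Leaving out each library in turn gave 4 to 2301 genes at 1 generation and 448 to 4882 at 30 generations against wild type, and 3768 to 7555 between the exposures. It gave 10 to 13, 3 to 12 and 12 to 15 lists, 2487 to 7087 genes in the F test, 0 to 1078 opposite calls and a covariance from −0.1332 to −0.05673. At 30 generations against wild type the hypoxia list ranged from −0.9479 to 0.9829 and GAPDH from −0.711 to 0.982, and between the exposures S100A4 ranged from −0.27 to 0.396, where leaving out wild type replicate 3, or for S100A4 30-generation replicate 3, turned the direction. Leaving out either library that stood apart raised the gene counts of all 3 comparisons.

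The covariance was −0.2028 with a pseudocount of 0.1 and −0.0547 with 5, which compress low values less or more. Without a filter, which adds genes near 0 to the adjustment, it was −0.04317, with 937 genes at 30 generations against wild type and 66 opposite calls. A filter of 5 FPKM, with fewer genes tested, gave 1205 genes and 3 lists at 30 generations against wild type, 3598 genes between the exposures and 2993 in the F test. Quantile normalization gave 976 genes at 1 generation, 3 lists at 30 generations against wild type and 206 opposite calls, and turned CALR to −0.91 between the exposures.

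Sample weights, whose estimation stopped before it converged, gave 8378, 8633 and 10863 genes in the comparisons in the order above, 7 lists at 30 generations against wild type, 11427 genes in the F test and 4836 opposite calls. They turned mitochondrially encoded mRNAs to −0.43 and TGFA to 0.41 at 1 generation, PCNA to −0.41 and GAPDH to 0.98 at 30 generations, and S100A4 to 0.46 between the exposures. Requiring an absolute log2 fold change of at least 1, which can only lower counts, left 344, 929 and 3426 genes. With an estimated correlation 2, 0 and 0 lists were called by camera, and with fry 10, 6 and 20. Over the comparisons fry made 12 list calls that camera did not at the preset correlation, and lost 13 of camera's.

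With only the 6 libraries compared, 1445 genes were called at 1 generation and 2 at 30 generations against wild type, with other libraries out of the pooled spread and fewer degrees of freedom. The replicate block over 9 libraries gave 327 genes at 1 generation and 68 opposite calls. The numbers did not pair wild type with 1 generation (r −0.0461, −0.0488 and −0.0135, 0 libraries closest to their own number) or the exposures (r −0.116, 0.152 and 0.0114, 3 libraries). Between wild type and 30 generations, the 4 libraries numbered 1 and 3 were closest to their own number, and those numbered 2 to number 1. The block within the 6 libraries, an alternative chosen after seeing the data, gave 0 genes at 1 generation and 0 at 30 generations against wild type in limma, with 2958 and 4279 at an unadjusted p under 0.05.

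Other alternatives were also chosen after seeing the data. Without the 2 libraries that stood apart, 7814, 9718 and 10969 genes were called, with 11561 in the F test and 4869 opposite calls. At 1 generation the hypoxia list turned to 0.43, mitochondrially encoded mRNAs to −0.37, TGFA to 0.48 and MT-ND3 to −0.38. At 30 generations KRT8 turned to 0.23, PCNA to −0.48 and GAPDH to 1.01 (1.006), and S100A4 turned to 0.40 (0.396) between the exposures. With GC content and length trends removed, 577 genes and 7 lists were called at 30 generations against wild type, 3288 genes between the exposures, 2545 in the F test and 50 in opposite directions, with a covariance of −0.0327. Between the exposures this turned TLR4 to 0.20, TLR6 to 0.052, CLDN3 to −0.16, SFN to −0.49 and HSPB1 to −0.93.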

Other observations

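Some lists held fewer than 5 genes at the tested level and were not tested as lists, and the genes named in this part were chosen after their values were seen. Of the gastric lineage markers, GATA6, TFF2 and CTSE were tested, and the highest value in any library was 10 FPKM, for TFF2. GATA6, a transcription factor of the foregut, rose by 0.89 at 30 generations against 1 generation (adjusted p = 0.0052 in limma, n = 3 in each group). No intestinal metaplasia marker was tested, since the highest value of any in the list was 0.296 FPKM, for LGALS4. Of the metallothioneins, which bind metal ions, MT2A rose by 1.34 between the exposures (adjusted p = 0.013). Of the immune and endothelial markers LYZ, TIE1 and PECAM1 fell between the exposures, by 1.09, 1.61 and 1.85 (adjusted p = 0.0046, 0.0055 and 0.006), with 6.76 FPKM for LYZ and 10.8 FPKM for TIE1 as the highest values in any library.

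Levels of glycolysis and hypoxia genes by library belong to no comparison. PGK1 stood at 69.6, 80.8 and 1172.6 FPKM in wild type replicates 1, 2 and 3, and at 102.1, 121.7 and 715.7 FPKM in the 30-generation replicates. LDHA stood at 830.1 and 520.1 FPKM, BNIP3 at 251.7 and 159 FPKM, ALDOC at 279.4 and 54.4 FPKM and ADM at 47.6 and 21.3 FPKM in replicate 3 of wild type and of 30 generations. GAPDH stood at 1010.5, 1048 and 10575.6 FPKM in wild type replicates 1, 2 and 3, but at 2071.4, 2063.7 and 1968.9 FPKM in the 30-generation replicates, so it was not raised in the latter replicate 3. VEGFA measured 40.3, 44.5 and 36.4 FPKM in the 30-generation replicates.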
